A study of Mus musculus with 97 samples.

How the data were processed

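Bulk RNA was sequenced from 92 libraries: 35 factor pairs in induced neurons, the starting embryonic fibroblasts, whole brain, and 8 populations sorted from mice. Single-cell libraries were made for 5 pairs, with 1 library each. Per the labels, factors were carried by lentiviruses under doxycycline, doxycycline was withdrawn after 8 days, and EGFP-positive cells were sorted on day 16. Per the labels, bulk libraries were mostly made from 10 ng of RNA with an ultra-low-input kit. The authors named Trimmomatic 0.32, STAR, HTSeq and DESeq2 for the bulk libraries, Cell Ranger 1.3.1 and STAR for the single cells, and mouse genome build mm10. The strand setting, the annotation and the filter on cells are not stated.

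The deposited bulk table holds raw counts per gene symbol for 23338 genes, all whole numbers. It uses older symbols in places, which were matched to the gene lists by a table of names. The deposited normalised bulk table, on a variance-stabilised scale close to log2, was not used. The deposited single-cell tables are in log2: each value is log2 of 1 plus the UMI count scaled so that every cell sums to the median total of the file. That scaling was undone, which gave whole UMI counts within a tolerance of 0.01 for 100% of the values. The file of 4 populations was identical for its cells to the file of 5, which was used. Bulk libraries held 12028024 to 45284933 counts. A count of 0 was set to a floor of 3 counts over the libraries of a group, and genes with 1 to 3 counts on the lower side were given as a ratio of counts per total with its exact binomial interval. Bulk reads carry no molecular identifiers, so intervals and floors cover counting error only.

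Groups came from the sample titles and factor labels. The labels give each induced library an alternate identifier that ends in a number, 2 to 6 (none for 6 induced libraries, the fibroblasts, the sorted cells or brain). Replicates with the same number had a median correlation of log2 CPM of 0.99 and those with different numbers 0.971, so the number was treated as a hint of a library batch. Replicate numbers do not pair libraries: over induced pairs, the differences between replicates had a median correlation of 0.0222. Whole brain was used as a level for genes of other cell types, and was added to the sorted populations in an alternative of 2 comparisons. It came from older mice than the sorted cells, and from another strain and kit.

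Comparisons between populations with their own libraries were made in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with a quasi-likelihood fit of 90 libraries and 44 populations, which left 46 residual degrees of freedom and had 5.73 prior degrees of freedom. Comparisons between families of factors used the factor pair, or for sorted cells the population, as the unit, with counts summed over replicates and the other factor as a covariate. Low counts were filtered by edgeR's rule for the groups compared, and factors of the TMM method scaled the libraries. P values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 fold changes are given with an SE derived from the test, the absolute log2 fold change over the square root of its F statistic. It is thus an approximation. Levels are given in CPM (counts scaled by the library total) with SD over libraries. The interaction of bHLH family and partner was tested as the difference of 2 fold changes over the 20 pairs of the complete block. Each pair was also tested against the fibroblasts, and genes called in all 35 were counted.

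The comparisons, 34 gene lists, tests, alternatives and the rule for naming genes were set before the data were examined. The interaction, the covariates made from list scores, the contrasts within alternate-id numbers of Atoh1 and Ascl5, the exclusion of 4 sorted populations and the looser filter on cells were added after the data were seen. Of the lists 32 were tested, by limma's camera with a correlation of 0.01 and again with an estimated correlation. The other 2, the transduced factors and the genes used for sorting, were left out because the design sets them. A list score is the mean log2 CPM of its members with a prior count of 2. Named genes are the 10 largest called changes in each direction with at least 10 CPM on the higher side, without predicted, ribosomal and mitochondrial genes, and the list members with the smallest adjusted p. Coordinates are of GRCm38 (mm10).

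Alternatives included DESeq2 1.42.0, size factors of the RLE method in edgeR, no filter on low counts, a test against a log2 fold change of 1 (glmTreat), libraries as units with and without the replicate number or the alternate-id number, each library or replicate left out, each factor left out, the 5 induced libraries made from less than 10 ng left out, and other reference pairs. Fits with a library left out kept the dispersion trend of all libraries and re-estimated the dispersion of each gene. A change in a count of more than 1.5-fold was taken as moved. Other splits of the samples were drawn where each group had at least 3, to at most 100 per comparison. Tests were run on simulated data with 200 changed genes in each comparison but sorted neurons against fibroblasts, the interaction and the counts over all 35 pairs. Of 4-fold changes 84 to 100% were recovered and of 2-fold changes 11 to 83%, with 2.52 to 6.5% false calls. Simulated counts followed the dispersion trend and changed genes were not taken from those of low level. The rates thus leave out the spread of single genes around the trend and differences in spread between populations. Relations between list scores were tested with 100000 permutations.

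Cells with at least 500 genes, 1000 UMIs and at most 10% mitochondrial UMIs were kept and doublets marked by Scrublet were removed (scanpy 1.11.5, Python 3.11.15). The kept cells were clustered on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. Each cluster took the name of the marker set with the highest median CPM in its summed UMIs. The sets were neuron-like, fibroblast-like, muscle-like, cycling, glia-like, immune-like, endothelial-like and epithelial-like, apart from the gene lists. Every cluster came out as neuron-like or fibroblast-like. Levels in single cells are CPM of the summed UMIs of a population, with exact intervals for counting error at the 95% level. Genes were named where they had at least 50 CPM and at least 2 times the next population. Other tools were numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, leidenalg 0.10.2 and matplotlib 3.10.9. The Ascl2 pair with a conflict between title and factor label was left out of comparisons between partners.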

Results

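Gene expression was measured in 97 mouse samples, 92 by bulk RNA sequencing and 5 by droplet single-cell RNA sequencing. In the screen, embryonic fibroblasts with EGFP at Mapt, the gene of the neuronal microtubule protein tau, were given a pair of transcription factors on lentiviruses, and EGFP-positive cells were sorted after 16 days. Each of the 35 pairs joined a proneural basic helix-loop-helix (bHLH) factor to a POU-domain factor or to the nuclear receptor Nr4a2, and had 2 bulk libraries (70 in all). The starting fibroblasts had 2 libraries and whole brain had 2. The other 18 came from 8 populations sorted from mice. Cerebellum, cortex, dorsal root ganglion, hippocampus and the high- and low-intensity cells of the medial habenula had 2 libraries each. The Pcdh21-positive mitral and tufted cells and the Pcdh21-negative cells of the olfactory bulb had 3 each.

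The induced-neuron libraries held 15176239 to 45284933 counts, the fibroblast libraries 43539214 and 36212064, the sorted libraries 12028024 to 35719485 and the brain libraries 19006953 and 29176154. Between 16876 and 22214 of the 23338 genes of the table had a count. Mapt had a median of 354 CPM in the induced libraries and 0.885 CPM in the fibroblasts. For each of the 17 transduced factors the median over its labelled libraries was above that over the other induced libraries. For Ascl5, Atoh1, Neurog2, Neurog3, Pou3f2, Pou3f4, Pou4f2, Pou4f3 and Nr4a2 each labelled library was above each other induced library and both fibroblast libraries, and for the other 8 factors at least 1 was not. Ascl2 in its pair with Pou3f2 stood at 2.05 and 1.84 CPM, below the fibroblasts (5.03 and 2.40 CPM). In the pair of Ascl2 whose title and factor label disagree, the 2 libraries held 4069 and 2591 counts of Pou1f1, which the title names, and 7 and 6 counts of Pou5f1, which the factor label names. That pair stayed out of the comparisons between partner factors. Neurog1 was low in the libraries labelled Neurog1 with Pou4f2, at 2.00 and 0.57 CPM, against up to 0.98 CPM in induced libraries without that label.

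The first comparison asked which transcripts separate the sorted EGFP-positive cells from the fibroblasts they were made from, with the equal-weight mean of the 35 pairs. Genes of the synapse and the neuronal cytoskeleton rose. All 30 pan-neuronal genes passed the test, among them Snap25, a vesicle fusion protein (log2 fold change 10.86 ± 0.420 SE; 1050 ± 292 CPM, SD, n = 70, against 0.421 ± 0.0872, n = 2), Scg3 (9.18 ± 0.435) and the presynaptic adhesion gene Nrxn1 (7.83 ± 0.389). Receptors and channels rose too: 13 of 17 ionotropic glutamate receptor genes (Gria4, 7.97 ± 0.567), 12 of 17 GABA-A and glycine receptor genes (Gabrg2, 7.92 ± 0.497), 24 of 30 voltage-gated channel genes (the sodium channel gene Scn3a, 8.30 ± 0.445) and 16 of 25 neuropeptide and dense-core vesicle genes (Pcsk2, 6.72 ± 0.497). All 22 cell cycle genes fell (Mki67, -4.42 ± 0.321), as did 28 of 30 fibroblast and mesenchymal genes (Snai2, -2.56 ± 0.242), all 12 microglia and macrophage genes (median log2 fold change -4.63; Cx3cr1, -5.40 ± 0.335; C1qa, -5.04 ± 0.444) and all 12 interferon response genes (median -1.92; Bst2, -3.16 ± 0.473).
Of the remaining lists, 20 of 30 skeletal muscle genes, all 5 glutamatergic genes and 5 of 11 neuronal nicotinic receptor genes rose and none fell, while 13 of 25 sensory neuron genes rose and 2 fell and 20 of 39 Hox genes rose and 3 fell. The largest rises were those of Stmn4, a stathmin of neuronal microtubules on chromosome 14 (66344210 to 66361680; 11.51 ± 0.628), Stmn3, Snap25, Nsg2, Chgb, Bex2, Scg5, Cplx1, Chga and the histone gene Hist3h2ba, which has near copies (1 count in the fibroblasts, ratio 1980 with a counting interval of 355 to 78100). The largest falls were those of Otor (-7.60 ± 0.465), the cartilage collagen gene Col2a1, Mmp13, Apoe, Mmp3, Dmp1, Crym, Ly86, Atp6v0d2 and Kcnj15 (-5.55 ± 0.315). Several of these were uneven between the 2 fibroblast libraries (Otor 68.0 ± 94.7 CPM, Col2a1 200 ± 270 CPM). Without fibroblast replicate 1, Otor and Crym were at -1.92 and -1.24 and did not pass, and Col2a1, Dmp1 and Mki67 were at -3.01, -2.21 and -2.46. Without replicate 2, Atp6v0d2 was at -3.42.
In all, 4398 genes were higher and 4932 lower, of 19954 tested. Adjusted over the list alone, the counts were 29 fibroblast genes, 25 channel genes, 13 GABA-A and glycine receptor genes, 21 muscle genes and 14 sensory genes, and otherwise equal to those above. The competitive list test called the pan-neuronal list (adjusted p = 1.14e-32), which held with an estimated correlation (adjusted p = 0.00935). The fibroblast, cell cycle, channel, glutamate receptor, neuropeptide, macrophage and GABA-A lists were also called (adjusted p = 1.32e-12, 4.93e-12, 2.61e-12, 9.52e-08, 2.13e-05, 2.49e-11 and 1.61e-05) and were not with an estimated correlation (adjusted p = 0.133, 0.116, 0.056, 0.056, 0.056, 0.0906 and 0.0906). The fibroblast libraries carry no alternate-id number, so no batch term could be fitted here.

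The same was asked of each pair on its own. Between 2791 and 4734 genes were higher than in fibroblasts (median 3943) and 1359 to 4185 lower, depending on the pair. 1330 genes were higher in all 35 pairs and 214 lower. They included 28 of 30 pan-neuronal genes and 17 of 30 channel genes among the higher, and 12 of 22 cell cycle genes among the lower. Of the fibroblast list 1 gene was lower in every pair, and no skeletal muscle gene was higher in every pair. The smallest rise of any pair was 10.32 on the log2 scale for Stmn4 and 9.86 for Snap25. The 35 contrasts share the same 2 fibroblast libraries, so they are not independent. In 5 simulated screens with no change and the same controls, no gene was higher in all 35 pairs, and at most 1 was at an unadjusted p.

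**Figure D1:**
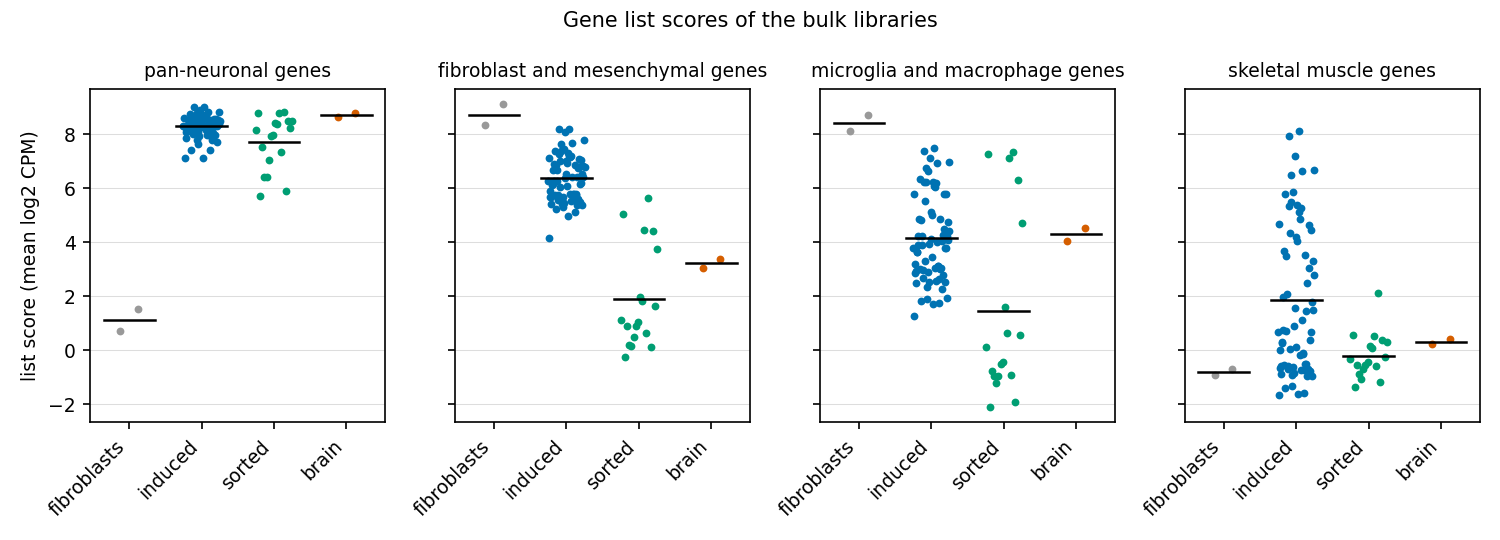
Mean log2 CPM of 4 gene lists in each of the 92 bulk libraries, by population group (points are libraries, lines are group means). The pan-neuronal list is higher in every induced and sorted library than in both fibroblast libraries. The fibroblast list is highest in the fibroblasts (9.11 and 8.34), and the macrophage and muscle lists spread widely between induced libraries.

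The sorted populations were set against the same fibroblasts as a reference for the cultured cells. Again all 30 pan-neuronal genes rose (Snap25, 11.58 ± 0.432; Scg3, 8.81 ± 0.430; Elavl4, an RNA-binding protein of neurons, 9.18 ± 0.469), and all 30 fibroblast genes fell (Prrx1, -6.80 ± 0.216). Receptor and channel lists rose, with 15 of 17 GABA-A and glycine receptor genes (Gabrg2, 10.27 ± 0.538), 14 of 17 ionotropic glutamate receptor genes (Gria4, 7.95 ± 0.569), 26 of 30 channel genes (Scn3a, 6.52 ± 0.411) and all 5 glutamatergic genes (the vesicular glutamate transporter gene Slc17a7, 8.73 ± 0.786). Of 39 Hox genes, which mark position along the body axis, 32 fell and none rose (Hoxc6, -7.19 ± 0.272). Of 12 oligodendrocyte genes, 10 rose, with a median log2 fold change of 8.08. The myelin gene Plp1 stood at 25600 ± 41800 CPM (n = 18) against 1.28 ± 0.294 (n = 2). All 12 macrophage genes fell (median -7.75).
Rises were largest for Ugt8a, an enzyme of myelin lipid synthesis (2 counts in the fibroblasts, ratio 98200 with a counting interval of 27200 to 811000), Nsg2, Snap25, Cacng3 (no count in the fibroblasts, at least 601-fold against a floor of 3 counts over the group), the myelin genes Mal and Plp1, Calb2, Resp18 (3 counts, ratio 5540, interval 1890 to 26800), Scg5 and Ppapdc1a (at least 355-fold). Falls were largest for Cd5l (-13.77 ± 0.801), Lyz2, Ccl8, Ms4a7, Atp6v0d2, Mmp3, Lilrb4, Marco, Otor and Col1a1 (-11.93 ± 0.613), several of them macrophage genes. Otor was at -6.28 without fibroblast replicate 1.
There were 4974 genes higher and 5385 lower, and 5197 and 6076 with cerebellum, cortex, hippocampus and the Pcdh21-negative bulb cells left out of the mean. With p values adjusted over the list alone, 33 Hox genes fell, and the other counts above were equal. The pan-neuronal, fibroblast, channel and Hox lists (adjusted p = 1.29e-25, 1.18e-23, 3.77e-12 and 5.96e-15), and the GABA-A, neuropeptide and glutamatergic lists (adjusted p = 8.17e-08, 2.21e-05 and 0.00144), kept their call with an estimated correlation (adjusted p = 0.0358 for the first and 0.0442 for the other 6). The glutamate receptor and oligodendrocyte lists (adjusted p = 2.56e-06 and 0.000257) did not (adjusted p = 0.0536 and 0.177).

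**Figure D2:**
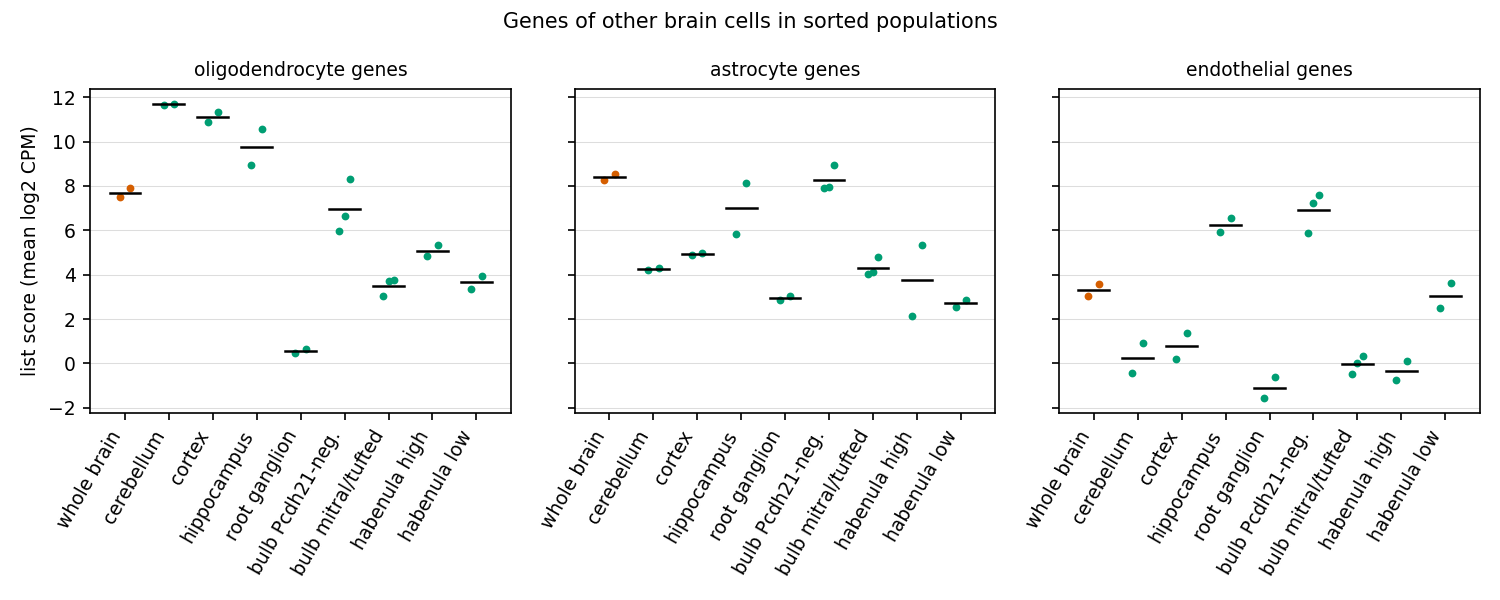
Mean log2 CPM of the oligodendrocyte, astrocyte and endothelial lists in the libraries of whole brain (orange) and the 8 sorted populations (points are libraries, lines are means). Oligodendrocyte genes stood at 11.64 and 11.71 in cerebellum, 10.87 and 11.35 in cortex and 10.56 and 8.94 in hippocampus, against 7.91 and 7.50 in whole brain.

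Direct comparison of the 35 induced pairs with the 8 sorted populations used counts summed per population. The clearest list was that of the Hox genes: 32 of 38 were higher in the induced cells and 1, Hoxd1, was lower (Hoxa10, 7.62 ± 0.338; 55.3 ± 20.2 CPM, n = 70, against 0.272 ± 0.407, n = 18). Fibroblast genes (21 of 30; Col5a1, 4.88 ± 0.387) and skeletal muscle genes (23 of 30; Tnnc2, 8.90 ± 2.23) were higher too and none was lower. Genes of mature subtypes were lower: all 16 medial habenula genes (with Tac2, -9.06 ± 0.664, a gene used in sorting, so that the design sets its level), 11 of 14 mitral and tufted cell genes (Eomes, -7.94 ± 0.670), 12 of 13 cerebellar neuron genes (Zic2, -5.16 ± 0.425), 17 of 25 sensory neuron genes (Scn10a, the sodium channel of pain-sensing neurons, -9.35 ± 0.809) and 4 of 5 GABAergic and glycinergic genes (Gad1, -8.78 ± 0.518). These lists mark cell types of only some of the 8 sorted populations. The pan-neuronal list was mixed, with 4 higher (the growth cone gene Gap43, 1.81 ± 0.484) and 8 lower (Snap25, -1.16 ± 0.221). Its median log2 fold change was -0.10 and its mean -0.19, while the list test pointed up. The sorted side was not uniformly rich in these genes. The pan-neuronal score was 5.9 and 5.71 in cerebellum, 7.93 and 7.54 in cortex and 7.32 and 7.98 in hippocampus. In the Pcdh21-negative bulb cells it was 6.42, 6.43 and 7.05. Whole brain had 8.79 and 8.64, and the other sorted populations had 8.17 to 8.82.
Genes of other brain cells moved with the sorted populations: all 12 oligodendrocyte genes were lower in the induced cells (median log2 fold change -11.06), as were all 10 astrocyte genes (median -4.89) and all 8 endothelial genes (median -5.31). The rises of greatest size were those of the acute-phase gene Saa3 (10.64 ± 1.05), Ccl8, Cd5l, H19, Tnnc2, Myl1, Hoxc10 (chromosome 15, 102966796 to 102971898; 7.96 ± 0.435), Marco, Agtr2 and Hoxa10. The largest falls were myelin genes: Mal (-12.77 ± 0.651), Ermn, Plp1, Mobp, Opalin, Gjb1, Mag, Mog, Fa2h and Ugt8a (-10.89 ± 0.704).
Of 18769 genes tested, 2625 were higher and 5904 lower. The counts adjusted over the list alone were 33 Hox genes, 22 fibroblast genes and 24 muscle genes higher, and equal for the lower ones named. The Hox list was called (adjusted p = 6.12e-37) and held with an estimated correlation (adjusted p = 0.00737). The fibroblast, oligodendrocyte, astrocyte, endothelial, cerebellar, habenula, muscle and mitral lists (adjusted p = 9.79e-24, 5.83e-10, 9.27e-07, 0.000754, 0.00315, 0.0041, 0.00466 and 0.0156) did not hold (adjusted p = 0.0568, 0.25, 0.226, 0.421, 0.103, 0.444, 0.708 and 0.444). Without cerebellum, cortex, hippocampus and the Pcdh21-negative bulb cells the counts were 3159 and 5436, and Gap43 (1.09) did not pass. Culture, age, sorting and library batch differ together between the groups and cannot be separated.

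The screen holds a complete block of 20 pairs, in which Ascl1, Ascl2, Neurog1, Neurog2 and Neurog3 were each joined to Pou3f2, Pou4f1, Pou4f2 and Pou4f3. In it, 12 Neurog pairs were compared with 8 Ascl pairs, with the partner factor as a covariate and the pair as the unit. Skeletal muscle genes stood apart: 28 of 30 were lower in Neurog pairs and none was higher, with a median log2 fold change of -4.58. Among them were Acta1, skeletal muscle actin (-7.25 ± 0.943; 4.10 ± 7.50 CPM, SD, n = 24, against 558 ± 798, n = 16), the troponin gene Tnnt3 (-6.95 ± 0.861) and the myosin light chain gene Mylpf (-5.16 ± 0.608). Neuropeptide and dense-core vesicle genes were lower (9 of 25; Scg5, -2.60 ± 0.259; the enkephalin precursor gene Penk, -3.12 ± 0.356), with Sst alone higher (2.52 ± 0.583). Nicotinic receptor genes went both ways: 3 of 11 were higher (Chrna3, 3.28 ± 0.524; Chrnb4, 3.14 ± 0.530) and 2 lower. Of 30 channel genes 9 were higher (Cacna1e, 2.15 ± 0.276) and 2 lower (Kcna2, -1.17 ± 0.175), and of 17 GABA-A and glycine receptor genes 5 were lower (Gabra2, -2.43 ± 0.303) and 1 higher (Glra2).
The largest rises were those of Reg3b (6.32 ± 1.53), the bHLH gene Nhlh2 (5.93 ± 0.551; chromosome 3, 102010111 to 102015492), Nhlh1, Cpne6, Vwa2, Mmd2, the dopamine receptor gene Drd1a, Chrna3, Neurod1 and Igfbpl1 (3.18 ± 0.607). The falls of greatest size were those of the receptor gene Gpr101 (-7.68 ± 0.401; chromosome X, 57496668 to 57503757), Myl1, Acta1, Tnnc2, the opiomelanocortin precursor gene Pomc (-7.06 ± 0.894), Tnnt3, Sln, Mybph, Myom2 and Des (-5.61 ± 0.823), 8 of them muscle genes.
Of 18225 genes, 733 were higher and 995 lower in Neurog pairs. With libraries as units and the alternate-id number as a covariate, the counts were 1098 and 1943, and 28 muscle genes were still lower. Adjusted over the list alone, 28 muscle genes, 12 neuropeptide genes and 10 GABA-A and glycine receptor genes were lower and 11 channel genes higher (5 lower). The muscle, neuropeptide and GABA-A lists were called (adjusted p = 5.81e-31, 1.13e-06 and 0.00118) and were not with an estimated correlation (adjusted p = 0.194, 0.0923 and 0.323). The macrophage and fibroblast lists, which vary between libraries, had median log2 fold changes of -0.16 and 0.26 here. Without replicate 1 of every pair the counts were 328 and 780, and without the Ascl1 pairs 308 and 613.

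**Figure D3:**
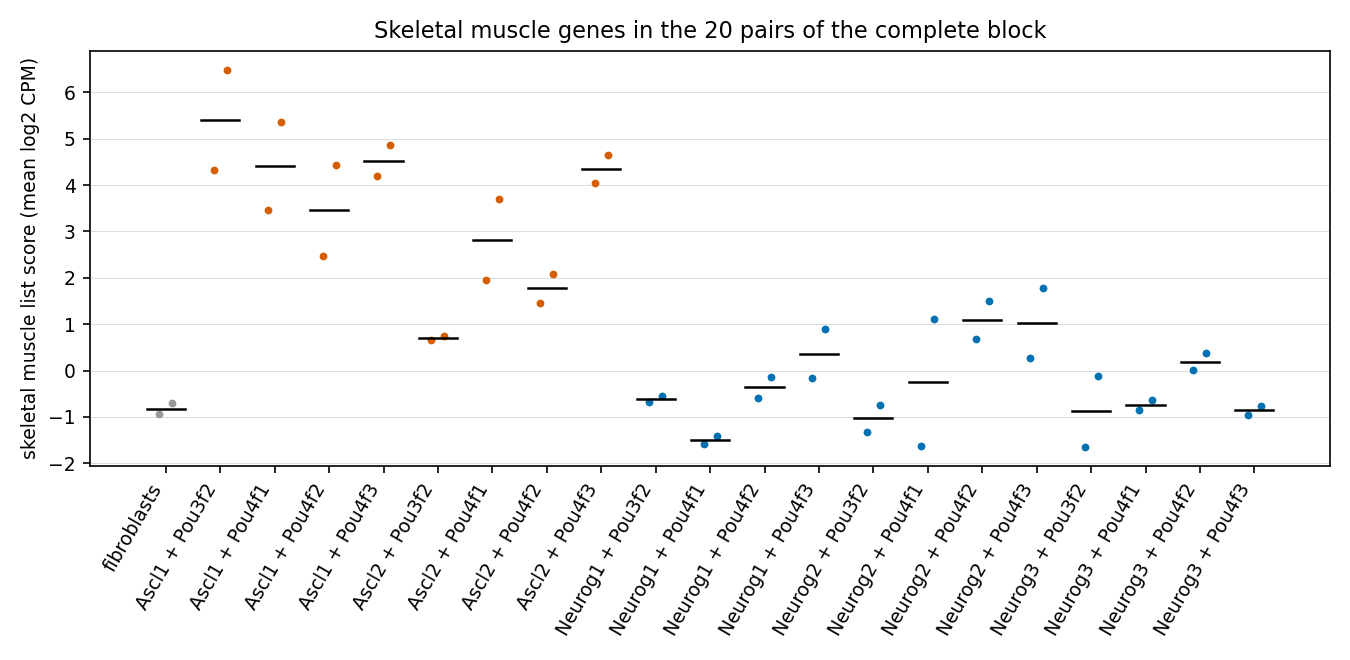
Mean log2 CPM of the skeletal muscle list in the libraries of the 20 pairs of the complete block and in the 2 fibroblast libraries (points are libraries, lines are means of the libraries of a pair, and orange marks Ascl pairs). All 8 Ascl pairs lie above both fibroblast libraries, and 7 of the 8 lie above the highest of the 12 Neurog pairs.

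In the same block the 15 pairs with a Pou4f factor were compared with the 5 with Pou3f2, with the bHLH factor as a covariate. Receptors for inhibitory transmitters were lower with Pou4f: 9 of 17 GABA-A and glycine receptor genes fell and none rose (Gabrb1, -2.74 ± 0.433; Gabra5, -2.32 ± 0.403; Gabrb2, -2.87 ± 0.505). Nicotinic receptor genes fell with them (3 of 11; Chrna4, -2.98 ± 0.362; Chrna7, -2.49 ± 0.413), as did the vesicular acetylcholine transporter gene Slc18a3 (-4.05 ± 0.679) and Chat, choline acetyltransferase (-2.35 ± 0.419), which are 2 of 5 cholinergic genes. Nefl (-3.69 ± 0.647) and Nefm (-3.19 ± 0.554), which code for neurofilament proteins, were lower. Of 24 sensory neuron genes 3 were higher and none lower: Sncg (3.39 ± 0.482), Fam38b, an older symbol of the touch channel gene Piezo2 (3.10 ± 0.598), and Pirt (3.19 ± 0.729).
Rises were largest for Gpc5 (5.17 ± 0.721; 53.8 ± 48.9 CPM, SD, n = 30, against 1.08 ± 0.637, n = 10), the cold receptor gene Trpm8 (4.37 ± 0.706), Nhlh1, Sorcs3, Avpr1a, Prom1, Sncg, St8sia6, Ano4 and Fam38b. The largest falls were those of the neuropeptide gene Cartpt (-5.80 ± 0.339; chromosome 13, 99898483 to 99910179; 2.64 ± 2.09 CPM against 134 ± 56.8), Hepacam2, Gpm6a, Vip (-4.67 ± 0.903), Neurod1, Slc18a3, Nefl, St18, Fgd5 and Kcnip1 (-3.53 ± 0.618).
Of 18606 genes, 311 were higher and 405 lower with Pou4f. With p values adjusted over the list alone, 11 GABA-A and glycine receptor genes, 5 nicotinic and 3 cholinergic genes fell and 5 sensory genes rose. The GABA-A and nicotinic lists were called (adjusted p = 3.58e-13 and 7.56e-05) and held with an estimated correlation (adjusted p = 0.0143 and 0.034). The cholinergic and sensory lists (adjusted p = 0.00501 and 0.00373) did not hold (adjusted p = 0.211 and 0.173). With libraries as units and the alternate-id number as a covariate the counts were 1463 and 1544. They were 845 and 1300 without the Pou4f2 pairs, 144 and 263 without the Pou4f1 pairs, 190 and 272 without the Pou4f3 pairs, and 180 and 259 without replicate 1 of every pair, where Hepacam2 (-5.20) and Pirt (2.42) did not pass.

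Whether the POU partner acts alike in both bHLH families was tested with an interaction term, added after the data were seen. The effect of Pou4f against Pou3f2 differed between Neurog and Ascl pairs for 22 of 19107 genes, 8 with a more positive effect in Neurog pairs and 14 with a more negative one. Nell1 stood at 571 CPM in Neurog pairs with Pou4f and 29.5 CPM with Pou3f2, and at 30.1 and 34.4 CPM in the Ascl pairs (difference of log2 fold changes 4.56 ± 0.815, adjusted p = 0.0409). Arhgef3 (2.55 ± 0.367) and the thyroid hormone receptor gene Thrb (2.35 ± 0.346) moved the same way. The neuronal sodium pump gene Atp1a3 was at 232 and 1180 CPM in the Neurog pairs and at 895 and 724 CPM in the Ascl pairs (-2.66 ± 0.389, adjusted p = 0.0127). Sparcl1 (-3.81 ± 0.397), Esrrg (-3.67 ± 0.663) and Cdh20 (-5.33 ± 0.947) were of the same kind. These 7 genes were chosen after their values were seen. With DESeq2 the counts were 122 and 112. Leaving out replicate 1 of every pair, 0 genes were more positive and 1 more negative, and without replicate 2 the counts were 3 and 2. With libraries as units and the alternate-id number as a covariate they were 968 and 1549, so the number of genes depends on the unit and the batch term.

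The block was also split into shares of variance, descriptively. Over the 2212 genes called for either factor, the bHLH factor took a median of 46.7% of the variance between pairs, the partner 25.3% and the remainder 23.5%, against 21.1%, 15.8% and 63.2% of the degrees of freedom. The bHLH share was the larger for 1477 of these genes, which were chosen by being called. Over all 11697 genes of at least 10 CPM in any pair, the shares were 20.4%, 30.1% and 43.7%, and the bHLH share was the larger for 4272.

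Pou1f1, the pituitary POU factor, was compared with the Pou4f factors over the 4 bHLH factors that had all of them (4 pairs against 12). Vip rose (4.52 ± 0.776), as did Sst (3.02 ± 0.493), both neuropeptide genes, together with the nicotinic receptor gene Chrna4 (3.02 ± 0.341), the GABA-A receptor gene Gabrd (3.13 ± 0.470) and the calcium channel gene Cacna1i (2.71 ± 0.417). Of 24 sensory neuron genes Sncg (-3.19 ± 0.580) and Isl1 fell and none rose. The rises of greatest size were those of the calcium channel subunit gene Cacna2d3 (4.66 ± 0.441; chromosome 14, 28904943 to 29722775; 160 ± 112 CPM, SD, n = 8, against 6.46 ± 5.10, n = 24), Sez6l, Vip, Vwc2l, Il1rapl2, Rasd1, Fam5c, the orexin receptor gene Hcrtr2, Arhgap36 and Ngef (3.10 ± 0.522). Falls were largest for Gpc5 (-6.40 ± 1.04), Klhl1, Trpm8, Mrap2, St8sia6, Aldh1a7, Stk32b, Unc13c, Sncg and Bcl11a (-3.04 ± 0.432).
In all 203 of 18273 genes were higher and 155 lower. The nicotinic (1 of 11 higher, 5 adjusted over the list alone) and GABA-A lists (1 of 17, 4 adjusted over the list alone) were called (adjusted p = 0.0127 and 0.00371) and were not with an estimated correlation (adjusted p = 0.45 for both). With libraries as units and the alternate-id number as a covariate the counts were 2067 and 1547. That fit lacked both libraries of Neurog3 with Pou1f1, which carry no number. Without replicate 1 of every pair the counts were 117 and 59. Against the Pou3f2 pairs in place of Pou4f, 1 gene was higher and none lower, and that gene was the transduced Pou1f1 itself. Against Pou3f2, Vip, Chrna4 and Arhgap36 were at -0.74, -0.24 and -0.22 and Sncg and Trpm8 at 0.17 and 0.33. Isl1 did not pass without replicate 1 (-1.44) or replicate 2 (-2.07), nor did Mrap2 (-4.31) and Trpm8 (-3.60) without replicate 1.

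Nr4a2, a nuclear receptor of dopamine neurons, was compared with the POU factors in Ascl1 and Ascl2 pairs (2 pairs against 8). Genes of inhibitory transmission rose: Slc6a5, the glycine transporter of glycinergic neurons (6.28 ± 0.360; 22.2 ± 13.1 CPM, SD, n = 4, against 0.287 ± 0.210, n = 16), and the GABA transporter gene Slc6a1 (4.74 ± 0.528), 2 of 5 genes of that list. Th, tyrosine hydroxylase, rose by 3.99 ± 1.05 on the log2 scale and the stress hormone gene Crh by 5.85 ± 0.603. Of 39 Hox genes 12 rose (Hoxc4, 1.98 ± 0.300), of 19 forebrain and midbrain factors 6 rose (En2, 2.88 ± 0.575), and of 15 hair cell genes 5 rose (Espn, 2.16 ± 0.415). Pan-neuronal genes fell (13 of 30; Tubb3, -1.91 ± 0.186; Stmn2, -2.12 ± 0.241; Syt1, -2.64 ± 0.319), as did 4 of 17 glutamate receptor genes (Gria2, -1.74 ± 0.179; Gria4, -3.51 ± 0.525), while 3 rose. The muscle regulator gene Myod1 rose (3.21 ± 0.786), with 4 of 30 muscle genes in all.
The largest rises were those of Trp73 (7.52 ± 0.354; chromosome 4, 154056249 to 154139875), Slc6a5, Crh, Car3, Necab2, Slc6a1, Scube1, Nxph4, Myoc and Nppa (4.30 ± 0.338). The falls of greatest size were those of the neurotensin gene Nts (-5.08 ± 0.760), Sncg, the adenosine receptor gene Adora1, Rgs20, the choline transporter gene Slc5a7, Cnih3, Gria4, Neto1, Tac1 and Kcnab1 (-3.26 ± 0.973).
Of 18833 genes 1191 were higher and 1703 lower. Adjusted over the list alone, 15 Hox genes, 7 regional factors, 7 hair cell genes, 3 inhibitory genes and 4 muscle genes rose, and 14 pan-neuronal genes fell. The pan-neuronal, muscle, Hox, regional, inhibitory and hair cell lists were called (adjusted p = 8e-06, 8e-06, 5.99e-05, 0.000168, 0.000878 and 0.0264) and were not with an estimated correlation (adjusted p = 0.276, 0.684, 0.619, 0.276, 0.435 and 0.276). With libraries as units and the alternate-id number as a covariate the counts were 482 and 1037, and Myod1 (1.93) did not pass. The fibroblast score was 7.12 and 7.14 in Ascl1 with Nr4a2 and 7.62 and 5.77 in Ascl2 with Nr4a2. Over the 4 POU partners its mean was 5.78 (SD 0.63) with Ascl1 and 6.41 (SD 0.77) with Ascl2. With the macrophage and fibroblast scores as covariates the counts were 638 and 1098, with 1435 of the 2894 genes called in both. Tubb3 (-1.87), Stmn2 (-2.28) and Syt1 (-2.63) passed there, and Th (5.28), Car3 (6.68), Espn (2.29), Myod1 (2.96), Sncg (-4.25) and Kcnab1 (-3.09) did not. Without replicate 1 of every pair the counts were 164 and 331, and without replicate 2 they were 1906 and 1514. Without replicate 1, Car3 (6.03), Espn (1.71), Myod1 (2.76), Rgs20 (-3.43), Sncg (-4.59), Slc5a7 (-4.34), Cnih3 (-4.37), Tac1 (-3.29) and Kcnab1 (-3.66; -3.05 without replicate 2) did not pass.

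Atoh1, a bHLH factor of hair cells and cerebellar granule cells, was joined to Pou4f3 only, and its 2 libraries were compared with the mean of the 5 other bHLH factors with Pou4f3. Of 15 hair cell genes 3 rose and none fell: Barhl1, a homeobox gene downstream of Atoh1 in several tissues (5.74 ± 0.552; 8.04 CPM against 0.184), Lhx3 (3.88 ± 0.458) and Pcp4 (2.16 ± 0.382). Of 16 medial habenula genes 5 rose, among them the nicotinic receptor gene Chrna3 (2.44 ± 0.355), Lrrc55 (2.23 ± 0.331) and the vesicular glutamate transporter gene Slc17a6 (3.11 ± 0.478; 121 ± 4.21 CPM, SD, n = 2, against 27.3 ± 23.5, n = 10). Of 11 nicotinic receptor genes 3 rose, Chrna3 among them. The neuropeptide gene Gal fell (-3.93 ± 0.686).
Rises were largest for Mmp3 (5.31 ± 0.898), Lcn2, Lhx3, Cd209g, Cd209f, the peripheral neurofilament gene Prph, Fam70b, Rasd2 (3.52 ± 0.344), Lhx2 and Slc17a6. Mmp3, Lcn2, Cd209g and Cd209f were high in replicate 2 of Atoh1 alone, and without it their log2 fold changes were -1.72, -0.31, -1.06 and -0.86. Prph was at 2.91 without it and did not pass. The largest falls were those of Gal, Prox1, Cntn6, St8sia5, Cdh8, Grm5, Tfcp2l1, Gsdma, Fam135b and Snca, the synuclein gene (-2.52 ± 0.370). Without replicate 1 of Atoh1, Pcp4 (1.76), St8sia5 (-2.53), Cdh8 (-2.58), Gsdma (-2.55) and Fam135b (-2.40) did not pass, and without replicate 2 Cntn6 (-2.72) and Gsdma (-3.08) did not, with St8sia5 at -4.78.
In all 303 genes were higher and 70 lower. With p values adjusted over the list alone, 3 hair cell, 7 habenula and 4 nicotinic genes rose. The habenula list was called (adjusted p = 1.61e-06) and held with an estimated correlation (adjusted p = 0.0122). The hair cell and nicotinic lists (adjusted p = 0.00012 and 0.000765) did not hold (adjusted p = 0.0517 and 0.154). The counts without replicate 1 of Atoh1 were 81 and 27, and without replicate 2 they were 114 and 10. The total was 234 or 216 without replicate 1 or 2 of Ascl1, 236 or 224 without those of Neurog2 and 211 without replicate 2 of Neurog3, and in each of these Cd209f did not pass (3.33 to 3.79), nor without replicate 2 of Ascl2 or replicate 1 of Neurog1. Without replicate 2 of Ascl2 or replicate 1 of Neurog3, 200 and 183 genes were higher. Against the Neurog1 and Neurog2 pairs, whose libraries carry the same alternate-id numbers, they were 143 and 71, with 106 of the 373 genes called in both. Gsdma was then at 0.59, and Chrna3 (1.09), Lhx2 (1.06), Pcp4 (1.48), Slc17a6 (1.86), Cd209f (3.16), Cd209g (3.29), Cntn6 (-1.61), Fam135b (-1.58), Snca (-1.03), St8sia5 (-1.24) and Tfcp2l1 (-0.95) did not pass.

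Ascl5 was likewise joined to Pou4f3 only. Its 2 libraries differed from each other (correlation of log2 CPM 0.849, the lowest of the 35 pairs, whose median was 0.979), so that many values below rest on either of them. The SE below come from a spread pooled over all populations and do not cover that difference. Skeletal muscle genes were higher than with the other 5 bHLH factors (27 of 30; Actc1, 5.21 ± 0.546; Mylpf, 5.16 ± 0.542), as were 24 of 30 fibroblast genes (Acta2, 4.17 ± 0.618), 17 of 22 cell cycle genes (Ccnb1, 3.19 ± 0.542), all 12 macrophage genes (Tyrobp, 3.93 ± 0.664) and 11 of 12 interferon response genes. Of 30 pan-neuronal genes 17 were lower (Tubb3, -1.69 ± 0.268; Syp, -1.86 ± 0.298) and Nefm was higher (1.68 without replicate 2, which did not pass). Macrophage genes stood at a mean log2 CPM of 7.48 in replicate 1 and 3.20 in replicate 2, and muscle genes at 3.06 and 6.67. The rises of greatest size were those of the atrial myosin gene Myl7 (8.38 ± 1.12), the steroid synthesis genes Cyp17a1 (7.62 ± 0.601; 17.2 ± 6.02 CPM, SD, n = 2, against 0.0970 ± 0.140, n = 10) and Cyp11a1, Upk1b, Hsd3b1, Myl1, Tnni2, Tnnc2, the noradrenaline enzyme gene Dbh and Tnnt3. Falls were largest for Ppp1r17 (-4.80 ± 0.623), Slco4a1, St8sia6, Stk32b, Spnb3, the ATP receptor gene P2rx3, Cdh10, Insm1, Atp2b2 and Chst9. Without replicate 1, Myl7, Dbh and Tyrobp were at 1.28, 0.53 and 0.55 and did not pass. Without replicate 2, Mylpf, Myl1, Tnni2, Tnnc2 and Tnnt3 were at 0.30, 1.63, 1.33, 0.31 and 0.92 and did not pass, and Actc1 was at 2.77.
In all 4687 genes were higher and 3634 lower. Adjusted over the list alone, 29 muscle, 24 fibroblast, 19 cell cycle, 12 macrophage and 11 interferon genes were higher and 18 pan-neuronal genes lower. Each of these lists was called (adjusted p = 9.33e-11, 2.33e-05, 2.03e-05, 0.000383, 0.0104 and 3.2e-08) and none was with an estimated correlation (adjusted p = 0.378, 0.435, 0.394, 0.408, 0.522 and 0.378). Without replicate 1 the counts were 2108 and 3153, and without replicate 2 they were 3419 and 1879. With DESeq2 size factors in edgeR they were 6335 and 2489, as the median of all genes moved from 0.29 to 0.51. Against the Ascl2 pair, whose libraries carry the same alternate-id numbers, they were 456 and 1557, with 1889 of the 8321 genes called in both. Of the genes named, Acta2 (2.23), Ccnb1 (2.44), Cyp11a1 (2.51), Dbh (0.94), Hsd3b1 (1.71), Myl1 (1.78), Myl7 (0.96), Mylpf (2.60), Nefm (0.19), Tnnc2 (1.88), Tnnt3 (1.97), Tyrobp (1.85) and Upk1b (2.81) did not pass against that pair.

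NeuroD2 with Pou4f3 was compared in the same way. Its replicates also differed (correlation of log2 CPM 0.917), and the SE below do not cover that difference. Genes of noradrenaline synthesis and transport rose: Dbh (7.12 ± 0.838), Th (6.13 ± 0.740), the noradrenaline transporter gene Slc6a2 (3.36 ± 0.487) and Ddc (2.52 ± 0.403), among 5 of 11 monoaminergic genes. Slc17a6 rose (4.93 ± 0.466; 470 ± 515 CPM, SD, n = 2, against 27.3 ± 23.5, n = 10), as did the forebrain factor gene Foxg1 (3.59 ± 0.659). Muscle genes (27 of 30; Ckm, 3.94 ± 0.525) and fibroblast genes (18 of 30; Fap, 2.80 ± 0.495) were higher and 6 of 30 pan-neuronal genes lower (Chga, -1.89 ± 0.293). Of 12 macrophage genes 5 were higher. The 2 libraries differed in these lists: replicate 2, made from 2 ng of RNA against 10 ng, had mean log2 CPM of 8.18 for fibroblast, 5.49 for muscle, 6.07 for macrophage and 7.41 for pan-neuronal genes, against 6.54, 2.77, 2.94 and 8.39 in replicate 1. The largest rises were those of Dbh, Th, the secretin gene Sct (5.85 ± 0.522; 12.8 ± 0.725 CPM against 0.227 ± 0.155), Upk1b, Akr1cl, Slc17a6, Col4a5, Aox3, Ccl11 and Col4a6. The falls of greatest size were those of Pomc (-4.29 ± 0.890), Sprr1a, Cntn6, Ppm1j, the NMDA receptor gene Grin2a, Rnf112, Ptgds, Cbln2 and Galnt9.
In all 1479 genes were higher and 601 lower. With p values adjusted over the list alone, 28 muscle, 21 fibroblast and 5 monoaminergic genes rose and 7 pan-neuronal genes fell. These lists were called (adjusted p = 7.77e-18, 2.11e-12, 0.000698 and 3.15e-08) and were not with an estimated correlation (adjusted p = 0.2, 0.26, 0.168 and 0.266). Without replicate 1 the counts were 1870 and 1379, and without replicate 2 they were 333 and 129. The lower genes numbered 380, 316, 367, 384, 385 and 397 without replicate 1 of Ascl1, replicate 2 of Ascl2, replicates 1 and 2 of Neurog1, replicate 2 of Neurog2 and replicate 1 of Neurog3. Without replicate 2 of NeuroD2 the log2 fold changes of Th, Upk1b and Ccl11 were -0.45, -0.89 and -1.52, those of Dbh, Ddc, Akr1cl and Sprr1a were 0.58, 0.21, 0.60 and -3.84, and none of the 7 passed. The falls of Cbln2, Galnt9 and Ptgds were then -5.09, -3.94 and -4.63. Without replicate 1 of NeuroD2, Aox3, Foxg1, Cbln2 and Ptgds were at 0.63, 1.32, -1.78 and -2.05 and did not pass, and Slc17a6 was at 2.48. The libraries carry no alternate-id number, so library batch cannot be separated from the factor.

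Among the sorted populations, mitral and tufted cells were compared with the Pcdh21-negative cells of the olfactory bulb, 3 libraries each. Of 14 mitral and tufted cell genes 13 were higher (Doc2g, 8.14 ± 0.404; 779 ± 132 CPM, SD, n = 3, against 3.24 ± 1.19, n = 3; Ntng1, 7.01 ± 0.441) and Cdkn1c was lower. Of 17 granule and periglomerular genes 16 were lower and none higher (Meis2, -4.89 ± 0.268; Gad1, the GABA-synthesising enzyme, -4.50 ± 0.529). Glutamatergic genes were higher (4 of 5; Slc17a7, 8.89 ± 0.651) and GABAergic genes lower (4 of 5; Slc6a1, -4.24 ± 0.523), and Th was lower (-3.98 ± 0.941). Genes of other cells were lower in the mitral and tufted libraries: all 8 endothelial genes (Pecam1, -7.43 ± 0.611), all 12 macrophage and microglia genes (Cx3cr1, -9.49 ± 0.953), all 12 oligodendrocyte genes, 28 of 30 fibroblast genes and all 22 cell cycle genes (Tyms, -2.30 ± 0.285).
Rises were largest for Ms4a15 (10.15 ± 0.886; chromosome 19, 10978303 to 10993299), Otop2, Cbln4, Fam110c (3 counts in the Pcdh21-negative libraries, ratio 556 with a counting interval of 190 to 2700), Kcnk15 (1 count, ratio 622, interval 111 to 24600), Slc17a7, Shisa3, Ush1g, Doc2g and Dkkl1. The largest falls were of genes with no count in the mitral and tufted libraries, lower at least 589-fold for S100a8, 268-fold for Tifab, 284-fold for S100a9, 210-fold for Upk1b, 214-fold for Ly6d, 216-fold for Plac8, 192-fold for Lcn2 and 188-fold for Ltf, against a floor of 3 counts over the group. Ccr5 (1 count, ratio 1550, interval 278 to 61200) and Pld4 followed.
In all 4723 genes were higher and 5924 lower. The counts named were equal when adjusted over the list alone. The mitral, granule, glutamatergic and endothelial lists (adjusted p = 1.75e-11, 6.18e-08, 0.00105 and 1.4e-06) held with an estimated correlation (adjusted p = 0.00133, 0.00399, 0.0347 and 0.0357). The GABAergic, macrophage, oligodendrocyte, fibroblast and cell cycle lists (adjusted p = 0.00583, 1.77e-05, 9.65e-05, 1.57e-09 and 1.4e-06) did not (adjusted p = 0.135, 0.234, 0.205, 0.205 and 0.205).

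High-intensity cells of the medial habenula were compared with low-intensity cells, 2 libraries each. The low-intensity cells held the cholinergic transcripts: Chat (-6.37 ± 0.678; 3.91 ± 0.218 CPM, SD, n = 2, against 290 ± 0.133, n = 2), Slc18a3 (-5.43 ± 0.746) and Slc5a7 (-4.08 ± 0.630), 3 of 5 cholinergic genes, and 5 of 11 nicotinic receptor genes (Chrna3, -2.52 ± 0.542). The high-intensity cells held more Tac1, the substance P precursor (5.46 ± 0.830; 766 ± 1.75 CPM against 15.5 ± 3.90), Cck (6.08 ± 0.740), the calcium-binding protein gene Calb2 (4.43 ± 0.797), and 8 of 17 GABA-A and glycine receptor genes (Gabra1, 4.81 ± 0.547). Gad1 was higher too (6.63 ± 0.795), with 3 of 5 GABAergic and glycinergic genes in all. All 8 endothelial genes were lower in the high-intensity cells (Cldn5, -5.34 ± 0.959), whose libraries had a mean log2 CPM of 0.11 and -0.76 for that list against 2.49 and 3.61.
The rises of greatest size were those of the phosphodiesterase gene Pde11a (7.27 ± 0.901; chromosome 2, 75985808 to 76339145), Gad1, Wif1, Cck, Vwc2l, Mab21l2, Spp2, Avil, Tac1 and the nerve growth factor receptor gene Ntrk1. The largest falls were those of Cfh (-6.86 ± 1.49), Synpr, Chat, Nfam1, Clec14a, Ctgf, Lmo3, Ly6c1, Nrgn and Slc18a3.
In all 722 genes were higher and 582 lower. Adjusted over the list alone, 4 cholinergic genes, 7 nicotinic genes and 8 endothelial genes were lower and 1 cholinergic gene, 11 GABA-A and glycine receptor genes and 3 GABAergic genes higher. The endothelial, cholinergic, GABA-A and nicotinic lists (adjusted p = 3.68e-12, 4.3e-07, 1.44e-08 and 2.27e-05) held with an estimated correlation (adjusted p = 0.00154, 7.32e-05, 0.0206 and 0.0377). The GABAergic list (adjusted p = 0.00197) did not (adjusted p = 0.0795). The counts were 747 and 237 or 390 and 268 without replicate 1 or 2 of the high-intensity cells, and 306 and 345 or 381 and 231 without replicate 1 or 2 of the low-intensity cells. Chrna3 (-2.23), Nfam1 (-5.95), Cfh (-6.07) and Ctgf (-6.28) did not pass without replicate 2 of the high-intensity cells. Nor did Cfh (-4.60) and Ctgf (-3.18) without replicate 2 of the low-intensity cells, and Ctgf (-5.81) without replicate 1 of the high-intensity cells, where Ly6c1 was at -11.08.

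Each pair was also set beside the sorted populations by Spearman correlation across the 2000 genes most variable among them, where genes are not independent replicates. Dorsal root ganglion cells were the closest for 22 pairs (median correlation over the 35 pairs 0.467), hippocampus for 6 (0.425), mitral and tufted cells for 6 (0.434) and Pcdh21-negative bulb cells for 1 (0.303). Over 500 genes the ganglion was closest for 30 pairs, and over 5000 genes for 7 (hippocampus for 14). With Pearson correlation it was closest for 17. The sorted libraries differ in genes of other cells: the oligodendrocyte score was 0.65 and 0.47 in the ganglion and 3.03 to 11.71 in the other populations. The pair closest to the Pcdh21-negative bulb cells, Neurog1 with Pou4f2, had macrophage scores of 6.93 and 7.36, against 7.1 to 7.33 in those cells. Whether genes of other cells set the ranking was not tested.

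**Figure D4:**
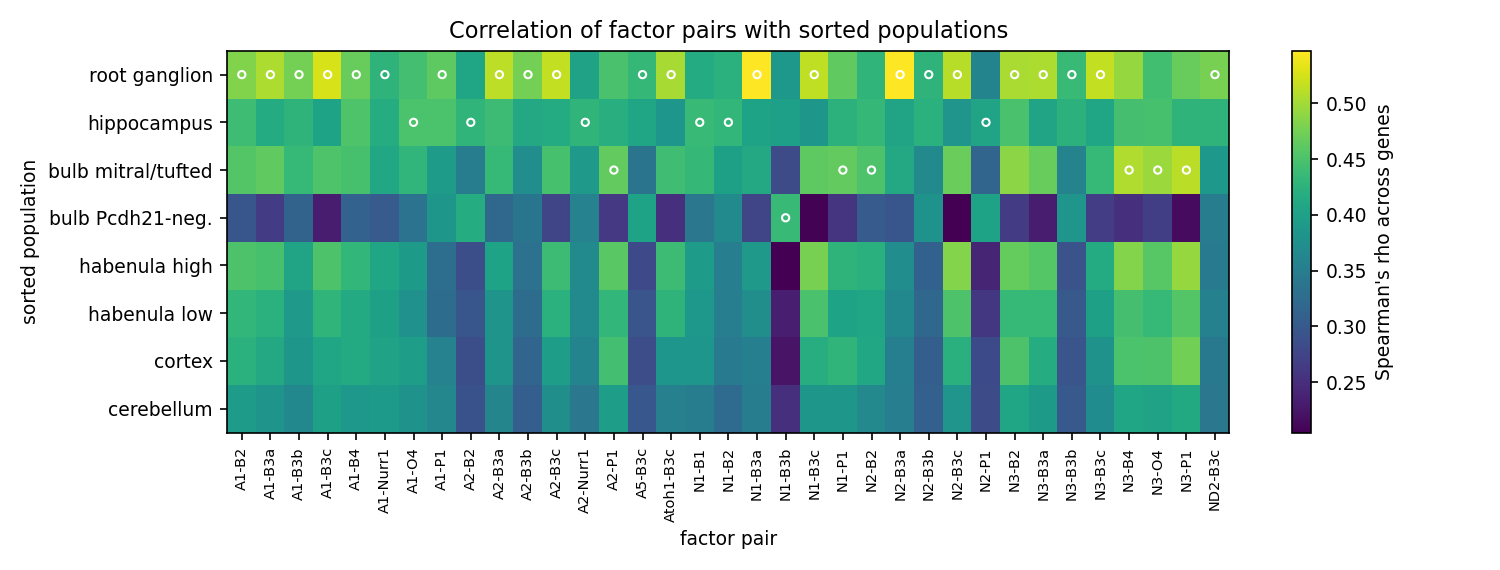
Spearman correlation across 2000 genes between each factor pair (columns) and each sorted population (rows), with circles at the highest of each column. A1, A2 and A5 are Ascl factors, N1 to N3 Neurog factors and ND2 is NeuroD2. B1, B2 and B4 are Pou3f3, Pou3f2 and Pou3f4, B3a to B3c are Pou4f1 to Pou4f3, O4 is Pou5f1, P1 is Pou1f1 and Nurr1 is Nr4a2.

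The single-cell file held 1322 cells of 5 populations, with 1 library each and so no replicates. After filters on mitochondrial share and doublets 781 were kept: 35 of Ascl2 with Nr4a2, 41 of Neurog1 with Pou4f1, 149 of Neurog3 with Pou3f4, 215 of Neurog3 with Pou5f1 and 341 of Neurog3 with Pou1f1. The last was a pool of EGFP-positive and EGFP-negative cells, and the others were EGFP-positive. Neuron-like cells made up 34 of 35 (97.14%, exact 95% confidence interval 85.08 to 99.93%), 41 of 41 (91.4 to 100%), 143 of 149 (95.97%, 91.44 to 98.51%) and 213 of 215 (99.07%, 96.68 to 99.89%) of the first 4, and 26 of 341 (7.62%, 5.04 to 10.97%) of the pool. Over all kept cells, those of the pool included, the Ascl2 with Nr4a2 cells had 75 UMIs of Slc6a5 (72.7 CPM), at least 43.9-fold above the other populations, which had none. Nppa (87.2 CPM, 35.6-fold above the next, interval 20.5 to 66.2), Pomc (272 CPM, 33.8-fold) and Car3 (at least 31-fold) followed. Neurog1 with Pou4f1 cells were highest in St8sia6 (88.8 CPM, 60.4-fold, 31 to 134.4), Unc13c (110.9 CPM, 19.4-fold) and Sncg (185 CPM, 15.9-fold). Among neuron-like cells alone the order changed. Hsd11b2 (48.2-fold, 24.8 to 102.6), Nppa (36.3-fold) and Itgb8 (28.8-fold) led with Ascl2 and Nr4a2, and Avpr1a (35.3-fold, 22.6 to 57.5), Ly6c1 (1 UMI in the next population, ratio 32.7, 5.7 to 1302.8) and St8sia6 (2 UMIs, ratio 23.5, 6.4 to 195.7) with Neurog1 and Pou4f1. Slc6a5, Pomc, Car3 and Sncg were then not among the first 5, with Pomc at 286 CPM against 28.3 CPM and Sncg at 185 CPM against 15.1 CPM in the Neurog3 with Pou1f1 cells. Slc6a5 and Car3 again had no UMI in the other populations. The floor of 3 counts rose from 1.65 CPM to 5.67 CPM with the few Neurog3 with Pou1f1 cells, which lowers the ratios of both genes. Over all kept cells, the leading genes of the Neurog3 pairs with Pou3f4 (Cacna1e, 3.5-fold) and Pou5f1 (Eef1a2, 3.4-fold) were closer to the next population. In neuron-like cells the skeletal muscle list made up 167 CPM (164 UMIs) with Ascl2 and Nr4a2 and 18.9 to 28.3 CPM in the other 4.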

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

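All tests on the 3 patterns weighed below, and the interaction itself, were chosen after the result was seen, while the other splits of the samples were planned for each comparison but the interaction.

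The effect of Pou4f against Pou3f2 differed between Neurog and Ascl pairs for 22 genes, Nell1, Atp1a3 and Sparcl1 among them, by a test of the difference itself. Over the 10 ways to divide the 5 bHLH factors into 3 and 2, the highest other split called 0 genes and the real one 22. These are too few splits for a share under 0.05. Without replicate 1 of every pair the count was 1, so most of these calls rest on having both replicates.

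Skeletal muscle genes were higher in Ascl than in Neurog pairs. Carry-over of cells still like the starting culture argues for scores at or below those of the fibroblasts, but 8 of 8 Ascl pairs lay above both fibroblast libraries. Those libraries are of the starting cells. Non-neuronal cells that had received the factors were not measured apart in bulk, so their carry-over stays open. Library batch alone is argued against by the 28 of 30 genes still lower in Neurog libraries with the alternate-id number as a covariate (median log2 fold change -4.50). A candidate explanation is the bHLH family of the pair, since 7 of the 8 Ascl pairs scored above the highest of the 12 Neurog pairs, and it remains a hypothesis found and tested on the same data.

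Macrophage genes varied between induced libraries and were highest in the fibroblast cultures. The genes moved together (median pairwise correlation 0.943, with 0.125 as the 95th percentile of random lists). Macrophages of the starting culture, or their RNA, among the sorted cells would do this, although cells were sorted for EGFP at Mapt. The kept single cells formed no immune-like cluster, and the highest median of immune markers in a cluster was 0.11 CPM. This argues against a group of macrophages in those single-cell libraries, and the bulk sorts were not examined in this way. Of the 12 genes of the list 10 were measured in the single cells. Expression by the induced neurons themselves is argued against by the neuron-like single cells, whose summed level, at the upper limit of its counting interval, was at least 27.8 times below the lower bulk library in 4 of 5 pairs. In the other pair, Neurog3 with Pou1f1, the level rests on 4 UMIs and that ratio was 6.17, so it cannot be told apart there from other cells in the sort. The alternate-id number took 44.4% of the variance, too little for library batch as the whole cause, with number 5 highest (mean 5.74, SD 1.32, 21 libraries). The factor pair as the whole cause is argued against by an intraclass correlation of 0.426 between replicates, and parts of both stay open.

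Oligodendrocyte genes were high in the libraries of sorted cerebellum, cortex and hippocampus. Of 12 such genes 10 were higher in all 6 libraries than in both whole-brain libraries, which is consistent with oligodendrocytes or their RNA among the sorted cells, although high-intensity EGFP or Tac2-Cre was used to sort them. In cerebellum and cortex the astrocyte score lay at least 3.29 log2 units below whole brain (-3.29 for the highest library). This argues against carry-over of all cells there in the proportions of whole brain. In hippocampus the astrocyte score was 8.13 and 5.85, against 8.52 and 8.26 in whole brain, while the oligodendrocyte score was 10.56 and 8.94 against 7.91 and 7.50. Carry-over in the proportions of whole brain would move both lists alike. The difference between them was at least 3.05 log2 units larger than in whole brain, which argues against carry-over in those proportions only. Whole brain came from older mice, another strain and another kit, so it is not a matched measure of the tissue of these regions. The endothelial score (5.92 and 6.54 against 3.04 and 3.57) and the macrophage score (6.31 and 4.71 against 4.54 and 4.06) were also above whole brain in hippocampus, so carry-over of several types of cell other than astrocytes stays open there. No biological explanation was tested.

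Splits of the populations take pairs that share a factor as separate. With that limit, chance is argued against for induced against sorted neurons (8529 genes called, 3928 in the highest of the other 99 splits of the populations). For Neurog against Ascl pairs the real split called 1728 and the highest other 15. This does not exclude chance for the bHLH families, because their label is set per factor and whole factors give only 10 splits. For Pou4f against Pou3f2 the real split called 716 and the highest other 671, which leaves a narrow margin, and with whole partners set apart Pou4f2 called more than Pou3f2 (1915). For Pou1f1 against Pou4f pairs 4 of 100 splits, the real one included, called as many genes as the real 358. The highest called 2509, several times as many, and each of the 3 others put Neurog pairs with Pou4f2 on the smaller side, which points to a structure of the samples set by those pairs, most of whose libraries carry alternate-id number 5. Pou1f1 against Pou4f gave 890 higher and 1105 lower genes with libraries as units, and with that number added as a covariate 2067 and 1547. The fit with the covariate left out both libraries of Neurog3 with Pou1f1, which carry no number. The fits thus differ in samples as well as in the covariate.

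The remaining splits are too few for a share under 0.05. Dividing the 5 bHLH factors gave 1728 genes for the real split and 48 for the highest other (10 splits). Of the 4 ways to set 1 partner apart, Pou3f2 gave 716, Pou4f2 1915, and Pou4f1 and Pou4f3 0 each, so that 2 splits gave at least as many as the real one. The 10 splits of the olfactory bulb libraries gave 9246 for the real one, fitted to the 6 libraries alone, and 0 for the highest other.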

How the results depend on the processing

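Totals below are genes called in either direction, and the cause of a change was not tested. The test against a log2 fold change of 1 (glmTreat) moved each comparison: induced neurons vs fibroblasts 4656, sorted neurons vs fibroblasts 5875, induced vs sorted neurons 2785, genes higher or lower in every pair 777, Neurog vs Ascl 292, Pou4f vs Pou3f2 68, Pou1f1 vs Pou4f 27, Nr4a2 vs POU 98, the interaction 1, Atoh1 43, Ascl5 1593, NeuroD2 245, olfactory bulb 6083 and habenula 418. With DESeq2, Pou4f vs Pou3f2 had 1308, Pou1f1 vs Pou4f 1039, Nr4a2 vs POU 4536 and the interaction 234. With libraries as units, Neurog vs Ascl had 3128, Pou4f vs Pou3f2 1920, Pou1f1 vs Pou4f 1995 and Nr4a2 vs POU 4973. Adding the replicate number as a block gave 3144, 1908, 1910 and 5358, and adding the alternate-id number instead gave 3041, 3007, 3614, 1519 and, for the interaction, 2517. The fits with the alternate-id number left out libraries that carry none, among them both of Neurog3 with Pou1f1. Against pairs with the same alternate-id numbers Atoh1 had 214 (Gsdma turned to 0.59) and Ascl5 2013. With macrophage and fibroblast scores as covariates Pou1f1 vs Pou4f had 870 and Nr4a2 vs POU 1736.

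Without replicate 1 of every pair the totals were 1108 for Neurog vs Ascl, 439 for Pou4f vs Pou3f2, 176 for Pou1f1 vs Pou4f, 495 for Nr4a2 vs POU and 1 for the interaction, which had 5 without replicate 2. The other 4 had 1633, 596, 412 and 3420 without replicate 2. With 1 library left out at a time Atoh1 had 108 to 300, Ascl5 5261 to 8702, NeuroD2 462 to 3249 and habenula 612 to 984. Without replicate 2 of Atoh1, Mmp3, Lcn2, Cd209g and Cd209f turned to -1.72, -0.31, -1.06 and -0.86 (up to 6.15, 5.25, 4.50 and 4.51 with other libraries left out), and without replicate 2 of NeuroD2 Th, Upk1b and Ccl11 turned to -0.45, -0.89 and -1.52 (up to 7.07, 6.72 and 5.68 with others left out). Without the Ascl1 pairs Neurog vs Ascl had 921. Without Pou4f1, Pou4f2 or Pou4f3 pairs Pou4f vs Pou3f2 had 407, 2145 and 462, and with all Pou3f pairs 1298. With Pou3f2 as reference Pou1f1 had 1 gene, and Vip, Chrna4, Arhgap36, Sncg and Trpm8 turned to -0.74, -0.24, -0.22, 0.17 and 0.33.

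With an estimated correlation the lists called numbered 1 for induced neurons vs fibroblasts, 7 for sorted neurons vs fibroblasts, 1 for induced vs sorted neurons, 1 for Atoh1, 0 for Ascl5, 0 for NeuroD2, 5 for the olfactory bulb, 4 for the habenula, 0 for Neurog vs Ascl, 2 for Pou4f vs Pou3f2, 0 for Pou1f1 vs Pou4f and 0 for Nr4a2 vs POU. Over all genes of at least 10 CPM the shares of variance were 20.4% for the bHLH factor, 30.1% for the partner and 43.7% left over. With 500 variable genes 0 pairs were closest to hippocampus (HIP), 3 to Pcdh21-negative bulb cells (OB-GC) and 2 to mitral and tufted cells (OB-MT). With 5000 they were 14, 0 and 4, and 7 were closest to the root ganglion (DRG). With Pearson correlation they were 11, 3 and 3.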

Other observations

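Across the 35 pairs the macrophage score followed the interferon response score (r = 0.968, rho = 0.957). Both permutation p values were 1e-05, the smallest they can give (adjusted p = 2.5e-05 and 1.67e-05, 5 relations computed). Without the 2 pairs farthest from the median (N1-B3b and A2-B2, Neurog1 with Pou4f2 and Ascl2 with Pou3f2) r was 0.963, and within alternate-id numbers 2 to 6 it was 0.904, 0.91, 0.825, 0.931 and 0.958 (n = 10, 7, 8, 13 and 13 pairs). The fibroblast score (r = 0.829, rho = 0.839) and the cell cycle score (r = 0.728, rho = 0.772) rose with it, and the pan-neuronal score fell (r = -0.54, rho = -0.49, adjusted permutation p = 0.00116 and 0.00382). Within numbers 2 to 6 that last relation had r = -0.395, 0.197, -0.796, -0.846 and -0.481, and only within number 5 did both coefficients pass at an unadjusted p under 0.05. For the muscle score no relation was shown over all pairs (r = -0.113, rho = 0.0504, permutation p = 0.522 and 0.773), with r of 0.51, 0.13, 0.559, 0.193 and -0.329 within numbers 2 to 6. The share of other cells in a sort may play a part in the macrophage, interferon, fibroblast and cell cycle lists, as the correlation of 0.943 between macrophage genes also allows. It was not tested in the bulk sorts. The kept cells of the EGFP-positive single-cell populations were at most 4.03% fibroblast-like and formed no immune-like cluster.

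Ascl1 and Ascl2 pairs were set against each other over 4 partners each. Of 32 lists, the muscle and unfolded protein scores were higher with Ascl1 in 4 of 4 partners (by 2.04 and 0.38 log2 units on average), and the macrophage, interferon, cell cycle, fibroblast and astrocyte scores were higher with Ascl1 in 0 of 4 (-1.62, -1.11, -1.01, -0.63 and -0.49). The exact permutation p was 0.0286 for the interferon and cell cycle lists, the smallest that 70 permutations can give, and 0.0571 for muscle (adjusted p = 0.365 for all 3). These permutations regrouped the pairs freely and did not keep the partners matched. So few permutations leave almost no room for a list to pass adjustment, and the absence of one that did says nothing. The highest muscle scores of the screen were those of Ascl1 with Nr4a2, at 8.11 and 7.92. In single cells, the neuron-like cells of Ascl2 with Nr4a2 carried 167 CPM of the muscle list against at most 28.3 CPM elsewhere, and 112 CPM of the GABAergic and glycinergic list (interval 91.9 to 134.8) against at most 4.15. A candidate explanation of the second is the effect of Nr4a2, with which Slc6a5 and Slc6a1 of that list rose in bulk. It was not tested, and in bulk the list did not keep its call with an estimated correlation.

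Replicates of some pairs differed in these scores. The macrophage score was 7.48 and 3.20 in the 2 libraries of Ascl5 with Pou4f3, and the list summed to 5870 and 632 CPM in those of Ascl2 with Nr4a2. The pool of Neurog3 with Pou1f1 cells, sorted for both signs of EGFP, held 315 fibroblast-like cells among 341, with Saa3 at 1121 CPM and Ccl2 at 470 CPM. Each single-cell population was set beside the 35 bulk pairs. Its own pair ranked 1 of 35 for Neurog3 with Pou1f1 (rho 0.791), 2 for Neurog3 with Pou5f1 (0.777), 3 for Neurog3 with Pou3f4 (0.747), 5 for Ascl2 with Nr4a2 (0.6) and 6 for Neurog1 with Pou4f1 (0.662). The filter on mitochondrial share removed 421 of 1322 cells, and Scrublet marked 120 of those left, 29 of 64 and 40 of 81 in the smallest populations. With a limit of 20% and doublets kept, neuron-like cells were 10.14% of the pool.

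Counts of factors outside the label of a pair were also seen, and their origin was not tested. In Neurog1 with Pou4f1, Pou4f3 stood at 24.29 and 18.16 CPM, above Pou4f1 itself at 7.03 and 7.31 CPM. In Neurog2 with Pou4f1 it stood at 50.9 and 20.88 CPM, against 15.28 and 10.24 CPM of Pou4f1. With Neurog3 and Pou4f1 the values were 11.07 and 11.12 CPM against 9.52 and 93.45 CPM. In Ascl pairs with Pou4f1, Pou4f3 was at most 0.69 CPM. Neurod2 stood at 70.12 and 100.5 CPM in Neurog3 with Pou5f1 and at 67.55 and 63.37 CPM in Neurog3 with Pou1f1. The libraries labelled NeuroD2 held 12.32 and 17.88 CPM.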
